A study of Homo sapiens with 22 samples.

How the data were processed

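The series used chromatin immunoprecipitation followed by sequencing (ChIP-seq) in NT2/D1 cells, a human embryonal carcinoma line that derives from a germ cell tumour, is pluripotent and differentiates when given all-trans retinoic acid (ATRA). The 22 samples combined 5 antibodies, against H3R2me2a (5 samples), H3K27ac (4), H3K4me1 (4), H3K4me3 (4) and control IgG (5), in CRISPR control cells and cells deleted for PRMT6, the arginine methyltransferase that places asymmetric dimethylation on arginine 2 of histone H3. Cells were grown without ATRA or with 1 µM ATRA for 3 days. The 5 region lists analysed here came from 2 of the samples, the H3R2me2a libraries of control cells with and without ATRA, and the other 20 samples were not analysed here.

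Libraries were handled with bcl2fastq, Bowtie2, MACS 1.4 and deepTools on build hg19 (GRCh37), per the submitters' processing notes, which give no role or order for these tools. Each list held region coordinates, a summit, the nearest transcript with its gene name and signed distance to its start, and a position class with a start window of 1250 bp and an upstream window of 5000 bp, per the file headers. The authors deposited whole-number tag counts per region with no scaling. A column of MACS tags accompanied clusters I and III, and a column named tagcount accompanied the promoter and enhancer lists, per the file headers. The library in which tagcount was read is not given in the sources used here. At the 202 cluster I regions, deposited under the library without ATRA, tagcount lay 0 to 8 tags above the MACS tags (median 3). Its lowest value was 35 in clusters I and II and 0 in cluster III. These values point to the library without ATRA as the one in which tagcount was read. Cluster II carried a pair of overlapping intervals per region, and the first of them was used because its coordinates matched the promoter and enhancer lists. The criteria for the clusters and for the promoter and enhancer classes, the control used in peak calling and the sequencing depth are also not given in the sources used here. Tag counts were therefore compared only within a column or between columns of the same region.

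Regions were joined on chromosome, start and stop. Overlap required at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals and odds ratios exact conditional 95% intervals, which cover counting error only. There was 1 library per condition, so no p-values were computed and no difference has a replicate check. Lists were also placed at random 1000 times on the same chromosome, inside the span covered by all regions there. The arms of chromosome 12 were split at 36 Mb, and densities used the 34.18 Mb up to the last short-arm region and the 95.05 Mb from the first to the last long-arm region. Medians of the ratio of tagcount to MACS tags carry 95% intervals from 1000 bootstrap resamples of regions. Distances to starts are the authors' own column. They were not set beside random placements, and the point of a region from which they were measured is not given in the sources used here. The last region on chromosome 1 ended at 249240536, beyond the hg38 chromosome 1 length of 248956422, so hg38 coordinates were never compared with the regions. GENCODE 44 and NCBI RefSeq tables supplied names, biotypes, gene lengths and chromosome arms only. Of 8816 nearest transcript identifiers, 8031 (91.1%) were found in GENCODE 44, and the rest were matched by gene name.

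A gene counted as having a region when the authors named it as nearest. The 20 gene lists were fixed before the data were examined. The background was the 6482 genes with a known length among the 6688 genes that the lists name (96.9%). For each gene list the share of its named members with a region was placed among 10000 random lists of the same size, drawn without repeats and matched on gene length in 20 bins, and the percentile describes these libraries. A list was said to lie outside the central 95% at percentile 2.5 or lower or 97.5 or higher. No protocadherin gene was in the background, which left 19 lists, 95 pairs of gene list and peak list and 19 differences between clusters II and III. At a nominal 5%, about 4.75 of the 95 pairs and 0.95 of the 19 differences would lie outside. Pairs share genes and small lists can rarely reach the limits, so the chance count of this procedure is not known. The procedure was tested on simulated data for cluster II with 30 genes per list among 6482 genes. Of 200 simulated lists, 1% passed percentile 97.5 with no planted enrichment, 43% with a planted odds ratio of 2 and 97.5% with 4. Most gene lists had fewer than 30 named members. Smaller lists, the lower limit, other peak lists and differences between clusters were not simulated, so these rates do not carry over to them.

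Genes named in the text followed a rule fixed with the gene lists. For each peak list it took the 10 genes with most regions, the 10 regions with most tags, 2 to 4 members of each gene list with most regions, and every member of the HOX, retinoid and pluripotency lists with a region. Some genes that this rule selects are not reported here. Further members of the H3K4 machinery, neural and numbered ZNF lists were named after their values were seen. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

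The alternatives tried were regions within 1 kb of each other merged, regions at or above their list's median tags or width, an overlap of 50% of the shorter region or of the promoter- or enhancer-list region, centres within 500 bp, autosomes only, start windows of 2 and 5 kb, a region within 1 kb or within 100 kb of the gene's start, random lists without length matching, cluster III thinned to the size of cluster II, neighbour windows of 50 and 500 kb, and random placement within 1 Mb. Alternatives added after seeing the data were all protein-coding genes as background, leaving out chromosome 12, its short arm or chromosome 19, a width filter, and subsets of cluster III by MACS tags or position class. In gene assignment, the nearest gene named by the authors replaced the planned gene body with 5 kb upstream. The planned base composition and the start distances to protein-coding genes alone were not run, because both need sequence or gene models of hg19.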

Results

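Genome-wide H3R2me2a, a histone mark placed by PRMT6, was described by 5 lists of enriched regions from control NT2/D1 cells. Clusters I (202 regions) and II (2098 regions) were deposited under the H3R2me2a library of cells without ATRA. Each cluster II region carried a pair of overlapping intervals whose libraries are not given, so cluster II may hold regions called in both libraries. Cluster III (6519 regions), a promoter list (4236 regions) and an enhancer list (4583 regions) were deposited under the library of cells given 1 µM ATRA for 3 days. There was 1 library per condition, so each value below has a counting interval and no replicate error. Sequencing depth is unknown. All coordinates are on hg19.

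The first question was how the lists relate to each other and where H3R2me2a lay. Every one of the 8819 regions was in exactly 1 cluster and in either the promoter or the enhancer list, with the same coordinates. Median widths were 426 bp in cluster I, 519 bp in cluster II and 514 bp in cluster III, and the lists covered 0.0914, 1.22 and 3.78 Mb. No promoter-list region overlapped an enhancer-list region.

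Strong cluster I regions lay in introns and next to genes on several chromosomes. The region with most MACS tags (139) was in an intron, 62253 bp from a start of KIAA0040 (chromosome 1, 175098789 to 175099972). It was followed by regions 2887 bp upstream of RNA5SP75 (103 tags) and 870 bp upstream of a start of RIF1, a replication-timing factor (102 tags). Regions in introns near SPTLC1 and MIR326 had 92 tags each. In cluster II, where only tagcount was at hand, the highest tagcount values on chromosomes were at the promoter of USP5, which encodes a deubiquitinase (1190, chromosome 12, 6961141 to 6962531), and at that of KMT2A, which encodes an H3K4 methyltransferase (1030, chromosome 11, 118306473 to 118307470). PRCC (867), FBXL19 (770), BAD (732) and SNX12 (728) followed. By number of regions, ACTB, LIN28A and SOX5 had 4 each in cluster II, after Y_RNA with 7.

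In cluster III the region with most MACS tags (765) was intergenic on chromosome 8 (37231676 to 37233987), 31427 bp from a start of the non-coding gene RP11-527N22.2. A region on chromosome 12 next to AC087237.1 had 670 tags. The promoter of the cell cycle gene CCND2 (chromosome 12, 4378428 to 4383643) had 654, and an intergenic region 17103 bp upstream of CRABP1, which encodes a cellular retinoic acid binding protein, had 646 (chromosome 15, 78614484 to 78616434). GAPDH and HIST4H4 promoters had 565 tags each. A region 13257 bp beyond a start of PCK1, a gluconeogenic enzyme gene, had 546 (chromosome 20, 56150804 to 56152827). After Y_RNA (45) and snoU13 (19), names shared by many gene copies, ETV6 had the most regions in this cluster (15, chromosome 12, 11803228 to 12038542), before TENM4 (12) and MALAT1 (11), and RNF220 and PKP2 had 9 each.

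The next question was how the clusters divide between promoters and enhancers. Cluster II was mostly promoter class and clusters I and III were mostly enhancer class. Of cluster II regions, 1503 of 2098 (71.6%, 95% interval 69.7 to 73.6) were in the promoter list, against 2708 of 6519 cluster III regions (41.5%, 40.3 to 42.8) and 25 of 202 cluster I regions (12.4%, 8.17 to 17.7). Cluster II therefore made up 35.5% (34.0 to 36.9) of the promoter list and 13.0% (12.02 to 13.99) of the enhancer list. Cluster III made up 63.9% (62.5 to 65.4) of the promoter list and 83.2% (82.0 to 84.2) of the enhancer list. Among regions at or above the median tagcount of their list, cluster II made up 64.3% and cluster III 35.0% of the promoter list, and 25.9% and 66.3% of the enhancer list, and the lowest tagcount of cluster II was 35. The odds ratio of promoter class was 3.55 for cluster II against cluster III (3.19 to 3.96), 17.9 for cluster II against cluster I (11.6 to 28.7) and 5.03 for cluster III against cluster I (3.29 to 8.01).

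**Figure D1:**
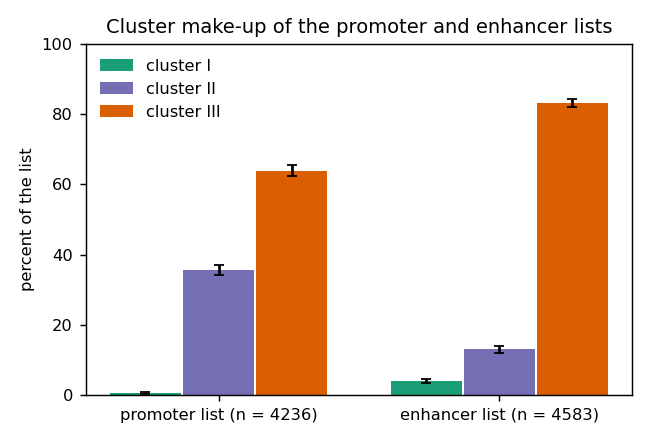
Percent of the promoter list (n = 4236 regions) and of the enhancer list (n = 4583 regions) that belonged to each cluster, with exact 95% intervals as error bars. Cluster II took 35.5% of the promoter list and 13.0% of the enhancer list.

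By tagcount, the column both classes share, the highest promoter-class regions apart from unplaced contigs were those of USP5, KMT2A, PRCC, FBXL19, BAD and SNX12, all in cluster II. RNVU1-18 (694) and C12orf57 (602) were also among the 10 highest. MALAT1 had 7 promoter-class regions, ATN1 and ACTB had 5 each, and FBXL14, TPI1, BCL9, NTF3, LIN28A and SNHG1 had 4 each. The enhancer-class region with the highest tagcount lay 3565 bp upstream of SEC22B (596, chromosome 1, 145091751 to 145093403). Next came regions at starts of small nuclear or nucleolar RNA genes, RNU11 (466), SNORD3A (450) and RNU5A-1 (441), and an intergenic region 11679 bp from a start of CYP1A2 (414). Of the 10 enhancer-class regions with the highest tagcount, 5 were nearest to such small RNA genes.

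Distances to transcript starts followed the same division. Within 1 kb of a start lay 74.9% of cluster II regions (73.0 to 76.7), 43.7% of cluster III regions (42.5 to 44.9) and 18.3% of cluster I regions (13.2 to 24.4). Median distances were 103, 2335 and 5849 bp. The share was 92.1% (91.2 to 92.9) in the promoter list and 12.1% (11.2 to 13.1) in the enhancer list. In the authors' position classes, introns held 42.6% of the enhancer list, intergenic sequence 31.6% and start windows 15.6%, whereas 94.2% of the promoter list lay in start windows. Within the enhancer list, cluster II regions were closer to starts than cluster III regions, with 24.2% (20.8 to 27.9) and 10.4% (9.47 to 11.4) within 1 kb.

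**Figure D2:**
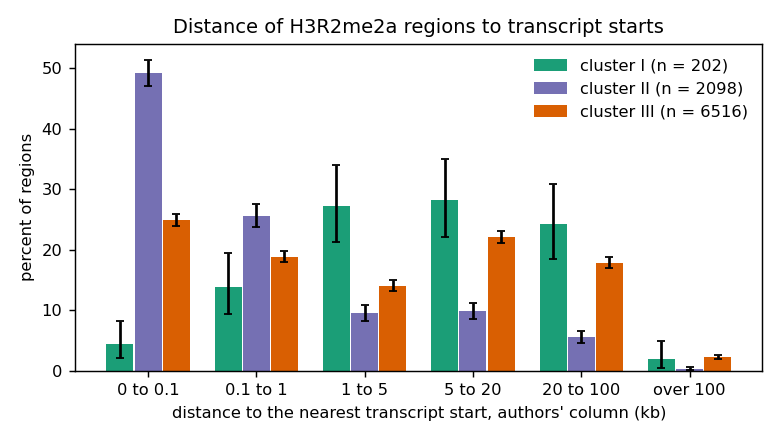
Percent of regions of each cluster by distance to the nearest transcript start in kb, as given by the authors, with exact 95% intervals as error bars. Within 0.1 kb lay 49.2% of cluster II, 24.9% of cluster III and 4.46% of cluster I regions.

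Genes of retinoid response and metabolism were marked in the enhancer list more often than genes of random lists. Of 29 genes in the retinoid list 14 were named, that is, given by the authors as nearest to a region. Of these, 13 had regions in cluster III, the cluster deposited under the ATRA-treated library (percentile 95.52, random median 71.4%). In cluster II there were 3 (percentile 25.27, random median 28.6%). Both cluster shares lay inside the limits set for random lists of named genes. Enhancer-class regions were nearest to 12 of the 14 (85.7%, percentile 99.95, random median 42.9%). Promoter-class regions were nearest to 5 (35.7%, percentile 2.05, random median 64.3%). Cluster III regions lay at the retinoic acid receptor genes RARA and RARB and 48393 bp from a start of the retinoid X receptor gene RXRA. They also lay at the uptake receptor gene STRA6, the binding protein genes CRABP1 and CRABP2, the retinoid-induced transglutaminase gene TGM2, the coregulator gene NRIP1, and the transcription factor genes MEIS1, MEIS2 and NR2F2. Cluster II regions lay in an intron 1907 bp from a start of STRA6 (tagcount 121), 8917 bp upstream of CRABP1 (58) and at the start of RDH11 (37).

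By the authors' gene names, retinoid genes with several cluster III regions included MEIS1 (4), STRA6 (3), RARB (3) and CRABP2 (3). A further intronic region on chromosome 3 (24776097 to 24776772, 83 MACS tags), which the authors named AC133680.1, was also matched to a gene of this list. Regions named RARB were intronic, with 75, 91 and 77 MACS tags and tagcount values of 10, 6 and 29 (the first on chromosome 3, 25263153 to 25263785). The 3 CRABP2 regions were promoter class, on chromosome 1 between 156674650 and 156677885, and the strongest had 151 MACS tags. For cluster III alone the retinoid list was at percentile 95.52 among lists drawn from genes the authors name and at 99.96 among lists drawn from all protein-coding genes. Its cluster II minus cluster III difference was at percentile 10.95 and 0.265 against these backgrounds. The promoter percentile was 51.39 with all protein-coding genes as background, and the enhancer percentile was 92.95 among regions at or above the median tag count.

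Of 39 HOX genes, which set position along the body axis, 8 were named, all in cluster III (percentile 96.11, random median 75%) and none in cluster II (percentile 3.135, random median 25%). They were HOXA2, HOXA3, HOXA4, HOXB1, HOXB3, HOXC4, HOXC13 and HOXD8. Their share in cluster II minus that in cluster III was at percentile 2.42 and at 5.39 without chromosome 12. The HOXA2, HOXA3 and HOXA4 regions were neighbours on chromosome 7, between 27141449 and 27170808. Random lists did not keep neighbouring genes together, so these percentiles may be too extreme. HOXA2, HOXA3 and HOXB1 had 3 regions each. The strongest was at a start of HOXA3 (chromosome 7, 27152579 to 27154222, 190 MACS tags). The 3 HOXA2 and 3 HOXB1 regions were enhancer class, as was the intronic HOXB3 region, and those of HOXA3, HOXA4, HOXC4, HOXC13 and HOXD8 were promoter class.

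Pluripotency genes were marked in all 3 clusters. Of 30 list members 8 were named, 7 of them by enhancer-class regions (87.5%, percentile 99.67, or 26.94 counting only regions within 1 kb of a start) and 3 by promoter-class regions (37.5%, percentile 4.915). Cluster I held a region 1342 bp upstream of a start of POU5F1, the gene of OCT4 (chromosome 6, 31139501 to 31140063, 70 MACS tags), and one at LIN28A, which encodes an RNA-binding protein (39 MACS tags). LIN28A also had 4 cluster II regions and 1 cluster III region, between 26729926 and 26745838 on chromosome 1. SALL4, a zinc finger factor gene, had 1 region in cluster II and 2 in cluster III. LEFTY1 and TRIM71 had cluster II regions, and SOX2, LEFTY2 and LIN28B had cluster III regions. The SOX2 region was 41642 bp from the start given by the authors (chromosome 3, 181471119 to 181471604, 40 MACS tags).

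Neural lineage genes had regions mainly in the enhancer list. Of 9 named of 38, 8 were in the enhancer list (percentile 99.41) and all 9 in cluster III (percentile 96.19, against a random median of 77.8%, with the cluster II minus cluster III difference at 5.77), led by ZIC2 (4 cluster III regions), MAP2 (3) and NES (2), with EN1, GLI3, POU3F1, POU3F3, SOX1 and TUBB3 at 1 each. Their percentile in the enhancer list was 62.56 when a region had to lie within 1 kb of a start and 90.64 among regions at or above the median tags or width. Of the WNT pathway list, 12 of 13 named genes were in cluster III, led by WNT5B (6), LRP6 (2) and WNT3A (2), at percentile 93.52. Of the Notch and Hedgehog list, 10 of 11 were in cluster III, led by NOTCH2 (5), HES1 (3) and PTCH1 (3), at percentile 89.09. The mesoderm (TBX5, MEOX1, NKX2-5, TBX6), endoderm (GATA4, PROX1), trophectoderm (KRT8, KRT18, TEAD4, TP63), and blood and immune (CD4, RUNX1, TAL1) lists had 4, 2, 4 and 3 named genes.

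Genes of the H3K4 methylation machinery, whose target lysine lies near arginine 2, were marked more in cluster II than in cluster III relative to random lists of named genes. Of 12 named genes 7 were in cluster II (KMT2D with 2 regions, KMT2A, KMT2B, SETD1A, KDM5B, RBBP5 and MEN1 with 1 each) and 5 in cluster III (KDM5A with 2, and ASH1L, ASH2L, KDM5C and SMYD3). The cluster II minus cluster III difference was 16.7 percentage points, against a median of -41.7 in random lists (percentile 98.59). With all protein-coding genes as background it was at percentile 97.05, inside the central 95%, and the share in cluster III, at percentile 1.27 among named genes, was at 70.35. Ribosomal protein genes were promoter class in 57 of 58 named cases (percentile 100), with RPL13 and RPL17 in cluster II and RPL10A, RPL13A and RPL14 in cluster III. Their shares in clusters II and III were 50% and 53.4%. In cluster III this was at percentile 0.175 of lists drawn from named genes and at 100 of lists drawn from all protein-coding genes, and the cluster II minus cluster III difference was at 99.91 and 65.7.

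Numbered zinc finger (ZNF) genes, many of which encode KRAB-type repressors, were also shifted toward cluster II. Of 176 named genes 109 were in cluster II (61.9%, 54.3 to 69.1, against a random median of 34.1%) and 71 in cluster III (40.3%, against 68.8%). With all protein-coding genes as background the list was at percentile 100 in cluster II and 36.72 in cluster III. Promoter-class regions were nearest to 160 (90.9%). Random lists were matched on gene length and not on promoter or enhancer class. Cluster II was 71.6% promoter class and cluster III 41.5%. Class may therefore account for shifts of gene lists toward either cluster, which was not tested. ZNF790 had 3 cluster II regions, and ZNF227, ZNF331, ZNF500 and ZNF565 were among those with 2. ZNF703 (5), ZNF367, ZNF423 and ZNF608 (3 each) led in cluster III. Olfactory receptor genes were nearly unmarked, with 2 of 415 named (OR2B11 in cluster II and OR10AC1P in cluster III), and none of the 53 protocadherin genes was named.

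Of 13 protein-coding genes in the list of reported PRMT6-regulated cell cycle genes, 5 were named. The reports behind this list are not given in the sources used here. Of 9 arginine methyltransferases 5 were named. Both lists lay inside the central 95% of random lists in every peak list (percentiles 58.9 to 94.23 and 30.38 to 85.1). With all protein-coding genes as background they were at 97.83 and 98.62 in the enhancer list. CCND2 had 7 cluster III regions, CCND1 had 2 in each of clusters II and III, CDKN1B had 2 promoter-class regions in cluster III, and CDKN2C had 1 in each of clusters I, II and III. CCND2 and CDKN1B lie on the short arm of chromosome 12, where regions were denser than on the long arm (below). Other genes of these lists may lie there too, and random lists were not matched on arm. PRMT6 had 2 cluster III regions at its start (51 and 40 MACS tags, chromosome 1, 107599041 to 107600119), PRMT8 had 4, PRMT1 and PRMT2 had 1 each, and CARM1 had 1 in cluster II. Polycomb genes were named in 7 of 30 cases, with PHC2 (3 regions) first in cluster III and MTF2 in cluster II. TGF-beta and BMP genes were named in 8 of 33 cases, 2 of them in cluster I (BMPR2 and ID1), and FGF pathway genes in 5 of 25, led by FGF3 (4 cluster III regions).

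**Figure D3:**
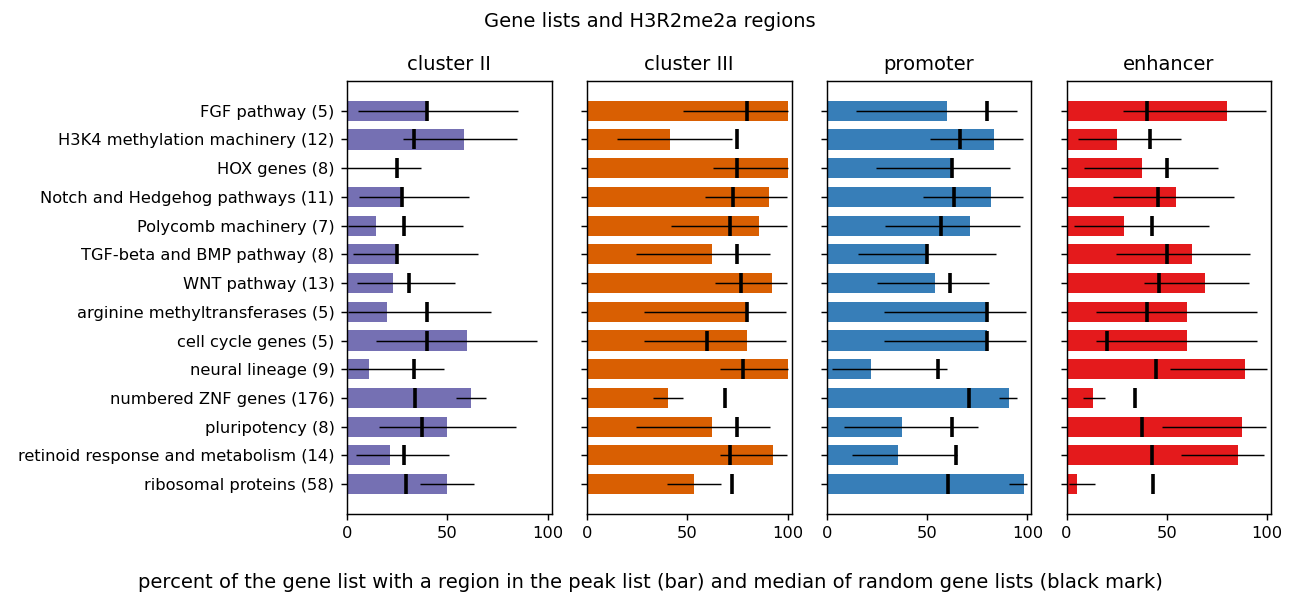
Percent of the named members of each gene list that had a region in cluster II, cluster III, the promoter list or the enhancer list, for lists with at least 5 named members, whose number stands in brackets. Bars carry exact 95% intervals and the black mark is the median of 10000 length-matched random lists, which was 34.1% for numbered ZNF genes in cluster II against 61.9% observed.

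Of 95 pairs of gene list and peak list, 18 lay outside the central 95% of random lists, against a nominal 4.75. Pairs of the same gene list share genes and are not independent. Every named gene had a region in some cluster and in the promoter or enhancer list. A high share in a peak list can therefore go with a low share in another by construction. Of 19 differences between clusters II and III, 4 lay outside (numbered ZNF, ribosomal protein, H3K4 machinery and HOX genes). Among regions at or above the median tags or width 10 pairs and 1 difference did, and the differences for ribosomal protein, H3K4 machinery and HOX genes were inside, at percentiles 96.23, 97.46 and 6.43. Lists with under 15 named members have wide intervals, such as 57.2 to 98.2% around the enhancer share of the retinoid list.

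Enhancer-class regions lay near promoter-class regions more often than random placement on the same chromosome gave, but at 50 and 100 kb not more often than every placement within 1 Mb. Within 100 kb of a promoter-class region were 1650 of 4583 enhancer-class regions (36%, 34.6 to 37.4), against a median of 22.7% and at most 24.98% over random placements on the same chromosome. By cluster the share was 43.9% (39.8 to 48.0) for cluster II, 35.1% (33.6 to 36.6) for cluster III and 28.8% (22.3 to 36.1) for cluster I. Random placement within 1 Mb of each region gave a median of 35.3% and at most 37.6%, which is above the observed share. Within 50 kb lay 22.0% (20.9 to 23.3), against a local median of 22.2% and at most 23.8%, and within 500 kb 76.3% (75.05 to 77.5), against a local median of 73.6% and at most 75.04%.

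Regions were unevenly spread over the chromosomes. Chromosome 1 held 19.2% of cluster III with 10.3% of protein-coding genes, and chromosome 12 held 13.0% of cluster III with 5.19% of protein-coding genes. Chromosome 19 held 11.6% of cluster II and 2.81% of cluster III, with 7.37% of protein-coding genes. On chromosome 12 the short arm (12p) carried 640 regions over 34.18 Mb and the long arm 390 over 95.05 Mb, a density on 12p 4.56 times that of the long arm (4.02 to 5.19). The ratio was 11.7 (4.29 to 39.65, 21 and 5 regions) for cluster I, 1.53 (1.08 to 2.14) for cluster II and 5.53 (4.79 to 6.41) for cluster III. ETV6, PKP2, SOX5, TMTC1, CCND2, CDKN1B, ATN1, FBXL14, TPI1, NTF3, GAPDH, HIST4H4, USP5 and C12orf57 lie on this arm. All are named above or among the genes with most regions, and this list is not complete. Random gene lists were not matched on chromosome arm, so counts of regions at genes on 12p may reflect the arm.

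**Figure D4:**
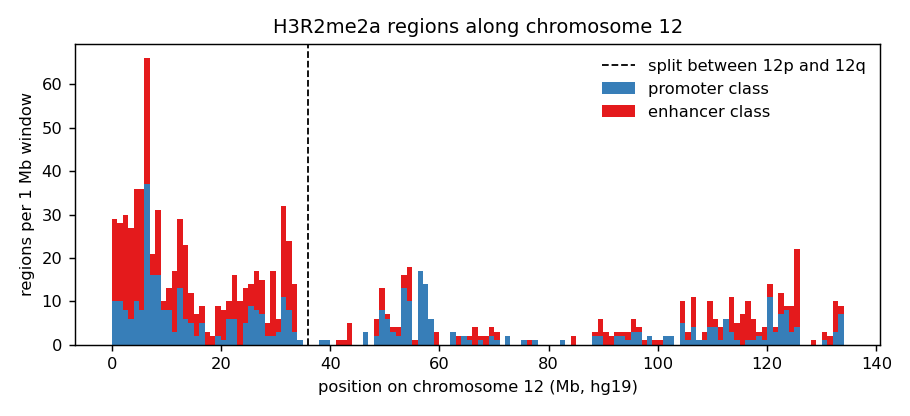
Number of promoter-class and enhancer-class regions per 1 Mb window along chromosome 12 (hg19), stacked, with a dashed line at 36 Mb between the arms. The short arm held 640 regions and the long arm 390.

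In cluster III both tag columns could be set side by side for each region. The ratio of tagcount to MACS tags had a median of 0.565 in 2708 promoter-class regions (bootstrap 95% interval 0.556 to 0.571) and 0.377 in 3811 enhancer-class regions (0.367 to 0.385). It was below 0.25 in 30 promoter-class regions (1.11%) and in 1075 enhancer-class regions (28.2%). The CRABP1 upstream region had 646 MACS tags and a tagcount of 48, the PCK1 region 546 and 64, and an exonic region of SDSL 464 and 18, whereas the CCND2 promoter had 654 and 418 and GAPDH 565 and 349. CCND2 and GAPDH lie on 12p, whereas the CRABP1, PCK1 and SDSL regions do not. An enhancer-class region of CCND2 had 254 MACS tags and a tagcount of 164. Across regions Pearson's r between the columns was 0.921 in the promoter class and 0.438 in the enhancer class. Without 12p it was 0.864 and 0.370, and regions are not independent replicates. The difference between the medians was 0.189 (0.176 to 0.1998), 0.104 (0.0775 to 0.143) among regions placed at a start and 0.342 (0.312 to 0.381) among regions with at least 100 MACS tags, a filter on the denominator of the ratio. The library in which tagcount was read is not given in the sources used here. At cluster I regions, deposited under the library without ATRA, tagcount lay 0 to 8 tags above the MACS tags. Its lowest value was 35 in clusters I and II and 0 in cluster III. These values point to the library without ATRA, so the ratio may compare the libraries without and with ATRA.

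**Figure D5:**
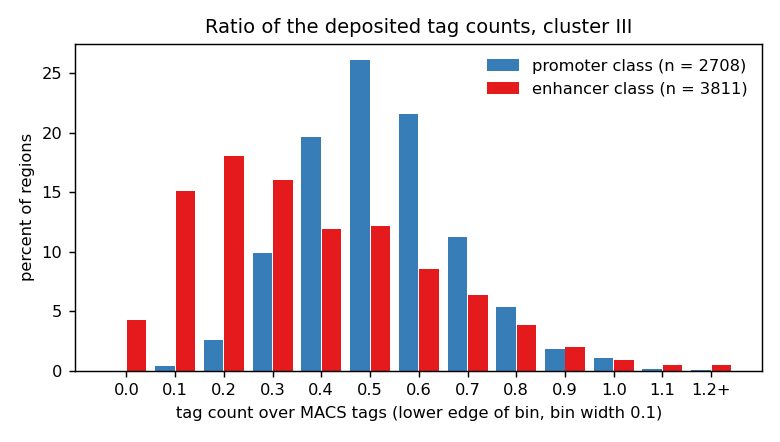
Percent of cluster III regions by the ratio of tagcount to MACS tags, in bins of 0.1, for the promoter class (n = 2708) and the enhancer class (n = 3811). Medians were 0.565 and 0.377.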

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

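The comparisons of genes on the short arm of chromosome 12 (12p) with those on all other chromosomes and the test of ZNF genes off chromosome 19 were set before their results were seen. The density ratios by position class and cluster were computed after the concentration was seen. A signal in sequence outside the chromosomes drew attention first, since 22 regions lay on 15 unplaced contigs and the highest tagcount values were there. They were 3527 on GL000205.1 and 2962 on GL000195.1, both in cluster II and nearest to Y_RNA, against at most 1190 on a chromosome. The second interval of cluster II regions, not used in the comparisons, was wider than the first in 84.9% of the 2098 pairs, with medians of 704.5 and 519 bp and a median summit distance of 31 bp.

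H3R2me2a regions of both classes were concentrated on 12p. Gene density is argued against for each class, because 45.7% of protein-coding genes on 12p (39.9 to 51.6) were nearest to a promoter-class region against 16.0% (15.5 to 16.5) on all other chromosomes and 23.3% on the long arm, and 32.3% (26.96 to 38.01) against 7.02% (6.66 to 7.39) and 7.90% for the enhancer class. The density ratio between 12p and the long arm was 3.38 to 8.65 over the 5 position classes, and 11.7, 1.53 and 5.53 in clusters I, II and III. Extra DNA copies of the arm, a known feature of germ cell tumours, and a higher level of the mark both stay open, since neither was tested and IgG libraries were not analysed here.

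Numbered ZNF genes were shifted toward cluster II, and many of them lie in clusters of genes on chromosome 19. Location on that chromosome is argued against as the whole cause, because 48 of 90 ZNF genes off chromosome 19 (53.3%, 42.5 to 63.9) had a cluster II region against a random median of 31.1%, at percentile 100. On chromosome 19 it was 61 of 86 (70.9%), at percentile 98.84 of random lists from that chromosome. Their random median was 61.6%, so there the excess over other genes of the chromosome was smaller than off it. Reads shared between similar ZNF copies were not tested and stay open, as do promoter class and a difference between cells with and without ATRA. Cluster II regions carry pairs of overlapping intervals whose libraries are not given. Cluster II against cluster III may therefore not compare cells without and with ATRA.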

How the results depend on the processing

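Alternatives that leave out chromosome 12 or 19 or the short arm, use all protein-coding genes, filter by width or subset cluster III, and those for arm density, were chosen after seeing the data, as were length matching, the 1 kb rule and the median filter for the differences between clusters. No paired analysis was possible because the 2 libraries compared share only 1 replicate number and no result came from a test. With 1 library per condition none could be left out. Of 819 values under alternatives, 43 of 75 main ones stayed within the main interval or 1.5 times the main count. Of the others, 659 stayed within the main interval, within 1.5 times the main count or inside or outside the central 95% of random lists as before, 28 came to lie outside it, 32 no longer did, 15 moved, and 10 that lay outside under the main or the other setting crossed percentile 50. Of 537 percentiles inside the central 95% under both settings, 77 crossed 50 and are among the 659. Regions at or above the median tags or width numbered 4477 of 8819. Under this filter the shares within 1 kb of a start were 13.1, 81.0, 46.0, 92.9 and 15.2% for clusters I, II and III, promoter and enhancer lists, 10 pairs and 1 difference lay outside random lists, and the 12p density ratio was 6.42. By tags, the odds ratio of cluster II against III was 4.69 (4.05 by width) and cluster II took 64.3% of the promoter list and 25.9% of the enhancer list, partly by construction since its lowest tagcount is 35. Windows of 2 kb gave shares of 25.2, 78.8, 48.6, 95.1 and 18.4%, and windows of 5 kb 45.5, 84.4, 57.8, 96.8 and 33.3%. With centres within 500 bp, 99.95% of regions matched exactly 1 cluster. Enhancer-class regions near promoter-class regions were 22.0% at 50 kb (8.14 points above placement on the same chromosome), 76.3% at 500 kb (21.6 points) and 33.5% without chromosome 12, and placement within 1 Mb left 0.70 points of 13.3. The tag ratio difference was 0.342 at 100 or more MACS tags and 0.104 at starts. With all protein-coding genes as background, percentiles that had lain or came to lie outside crossed for H3K4 machinery (70.35) and ribosomal proteins (100) in cluster III, olfactory receptors in cluster II and the enhancer list (0), retinoid genes in the promoter list (51.39) and ribosomal proteins in the enhancer list (50.37). Within 1 kb of a start such percentiles crossed for TGF-beta and BMP genes in cluster I (47.73), pluripotency genes in the enhancer list (26.94) and ribosomal proteins in cluster III (91.66), and under the median filter for TGF-beta and BMP genes in cluster I (43.78). Apart from the filter, the causes were not tested. Depth, which is unknown, limits all counts of regions. The planned base composition and distances to protein-coding starts were not run.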

Other observations

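All comparisons in this part were chosen after the results were seen. Arm 12p stood apart in tag counts as well as in number of regions. In cluster III, promoter-class regions on 12p had a median of 86 MACS tags and a tagcount of 63.5, against 51 and 29 elsewhere, and enhancer-class regions had 60 and 37 against 48 and 18. Of 105 regions on 12p with a tagcount of at least 100, 73 (69.5%, 59.8 to 78.1) were in cluster III, whereas elsewhere 27 of 639 (4.23%, 2.80 to 6.09) were. CCND2 (tagcount 418), HIST4H4 (395), GAPDH (349) and YARS2 (283) were among those on 12p. In all of cluster III, 4768 regions (73.1%) had a tagcount below the lowest value of clusters I and II, 35.

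Some genes carried regions of several clusters side by side. At CRABP1 a cluster III region lay 17103 bp upstream, a cluster II region 8917 bp upstream and another cluster III region 135 bp upstream of the start (chromosome 15, 78632290 to 78632859). At RIF1 a cluster I promoter-class region ended at 152265895 on chromosome 2 and a cluster III promoter-class region began at 152266106. CDKN2C had a cluster II region from 51436104, a cluster I region from 51437079 and a cluster III region from 51439417 on chromosome 1, all enhancer class.

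Among all 20020 protein-coding genes, 4515 (22.6%, 22.0 to 23.1) were nearest to a region of any list, 1571 (7.85%) to a cluster II region and 3109 (15.5%) to a cluster III region. Against random lists drawn from all of them, retinoid genes (13 of 29), Notch and Hedgehog genes (10 of 27) and WNT genes (12 of 44) were at percentiles 99.96, 99.44 and 97.88 in cluster III, and the H3K4 machinery (7 of 22) was at 99.94 in cluster II. Among lists drawn from named genes these were 95.52, 89.09, 93.52 and 97.21, all inside the central 95%. Random lists were not matched on chromosome arm, so list members on 12p may add to these percentiles. The cluster II minus cluster III difference was at percentile 0.265 for retinoid, 1.07 for HOX and 2.27 for neural lineage genes, and among named genes at 10.95, 2.42 and 5.77.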
